A study of Oryza sativa with 4 samples.

How the data were processed

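Messenger RNA was profiled by RNA sequencing in rice (Oryza sativa) seedlings of the japonica cultivar Nipponbare and the indica cultivar 93-11. Per the labels' protocols, seedlings 15 days old were moved from a greenhouse at 28 °C by day and 25 °C by night to 4 °C ± 1 for 33 h or left untreated, and the aerial parts were pooled into 1 library per cultivar and treatment. The 4 groups therefore hold 1 library each, and p-values measure only the spread between these pools. Messenger RNA was taken from total RNA with oligo(dT) beads and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Whether strand was kept or used in counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

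The deposited values are in RPKM, reads per kilobase of gene model scaled to the library's total, 1 value for each of 55985 gene identifiers in each library. Bowtie2 2.0.6, TopHat2 2.0.9 and HTSeq 0.5.4p3 are named in the submitters' processing notes, with no role or order. The genome build, the gene annotation and whether reads of 93-11 were mapped to the genome of another cultivar are not given in the sources used here. Loss of reads at sequence differences would then lower values in 93-11, and reads shared by near-identical genes could be split or dropped, so neighbouring copies such as OsDREB1A and OsDREB1B, RAB16A and RAB16B, or TIFY11A and TIFY11C are uncertain as single genes.

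Depth was worked out from the values. For each of the 36941 genes above 0, 1 whole gene length and 1 whole library total per library turned every value into a whole number of reads, within the rounding of the values. With totals shifted by 1 or 2 percent, 0 of 500 genes with at least 20 reads in every library could be solved. The library totals were 13482486 for Nipponbare chilled, 12671333 for Nipponbare untreated, 13012799 for 93-11 chilled and 16682882 for 93-11 untreated. Reads of a gene are known only up to a common whole factor, and those used here sum to 97.7 to 98.1 percent of the totals, so counting intervals err on the wide side. Counting intervals and floors (3 reads where a library has 0) cover counting error only, since PCR copies are not independent molecules.

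The design written before the data were examined assumed read counts. Since the files hold RPKM, the test listed beforehand for normalized values was used: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(RPKM + 1), with terms for cultivar and treatment, over the 19466 genes with at least 1 RPKM in at least 2 libraries. Values were first scaled by trimmed mean of M-values (TMM) factors computed from the recovered reads, trimming 0.3 of ratios and 0.05 of intensities. The fit has 1 residual degree of freedom. A gene's own spread in it is the disagreement of the 2 cultivars' responses, or for the cultivar term that of the 2 conditions' differences. To this limma adds a prior worth 4.26 degrees of freedom, drawn from genes of similar level. An SE thus rests more on that prior than on the gene's own disagreement. P-values were adjusted by the Benjamini-Hochberg method over all genes and called under 0.05. Fold changes on the log2(RPKM + 1) scale understate the change of low genes. Unless another scaling or setting is named, adjusted p-values are from this limma fit.

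No group has more than 1 library, so no test within a cultivar, within a condition or of the difference between responses was possible. For these, log2 ratios of scaled reads (0.5 reads added) are given with exact conditional binomial (Clopper-Pearson) 95% intervals, and the difference of the 2 responses with a Wald 95% interval. A gene counted as beyond 2-fold by size when its whole interval lay beyond 2-fold. Such counts compare libraries, not conditions.

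Gene names came from 24 lists of rice loci fixed from general knowledge before the data were examined. The RefSeq gene table (assembly GCF_034140825.1 ASM3414082v1) holds 0 of the files' identifiers, so a name was used only where that table places its symbol or a synonym on the same chromosome and in the same gene order. Some synonyms used for this were added after the table was seen. The pairing of name and identifier itself thus rests on general knowledge that the table did not contradict. This held for 152 of 259 loci; 97 were not in the table and are counted without names in an added alternative, 7 lay on another chromosome, 2 shared an entry and 1 was out of order. No descriptions come with the identifiers, so the gene families planned by description keyword were not run, and no coordinates are given. Measured members of a list are those that passed the filter of the test. For each list, members past the test are counted over all genes tested and adjusted over the list alone. The median fold change is set among 10000 random lists of the same size matched on mean expression in 20 bins. Named genes follow a rule fixed beforehand, with RPKM in place of CPM: the 10 highest and 10 lowest fitted changes among named genes past the test, beyond 2-fold by size on the same side in both cultivars and with at least 10 RPKM in the higher library of each; up to 8 named genes each way for the response difference and for the cultivar term; and from each list the 2 members with the largest fitted change and the 2 with the highest mean. For unnamed genes at most 2 identifiers each way are given.

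The fit was tested on simulated data of 18553 genes with the real levels, totals and a spread of 0.25 log2 units, for the chilling effect shared by both cultivars. Of changed genes, 22.0 percent were called at 2-fold (11 of 50), and all were called at 4-fold (48 of 48), 8-fold (46 of 46) and 16-fold (50 of 50), and 1 of 18359 unchanged genes was called. Few genes were changed in this simulation, by the same fold in both cultivars, whereas the real fit called 9063 of 19466 for chilling. Adjusted p depends on the share of changed genes, so these rates do not carry over to the real fit. Intervals were checked on reads drawn with counting error alone and with known totals. They covered the true value in 95.6 percent of 19353 genes for ratios and 95.1 percent of 19466 for response differences. The spread of 0.25 was not part of that check, so it says nothing about how often they cover a difference between conditions. Alternatives covered the scaling, the pseudocount (0.1), the filter, the fold bound (4-fold), thinning to the smallest total, the prior (2 reads) and the model without the other factor. Ranges of adjusted p for named genes are over 10 alternatives: the other scalings, the pseudocount, both filters, the model without the other factor and voom weights. Python 3.11.15 was used for the rest.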

Results

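The data were 4 RNA-seq libraries of the aerial parts of rice seedlings 15 days old, 1 pool for each combination of 2 cultivars and 2 treatments. Nipponbare is a japonica cultivar and 93-11 an indica cultivar, and chilled seedlings had spent 33 h at 4 °C. Library totals, recovered from the values, were 13482486 reads in Nipponbare chilled, 12671333 in Nipponbare untreated, 13012799 in 93-11 chilled and 16682882 in 93-11 untreated. Of 55985 genes listed, 28206, 29242, 27969 and 30127 were above 0 in these libraries, in that order. The 10 most abundant genes took 4.8 percent of reads in each chilled library, 9.3 percent in untreated Nipponbare and 10.9 percent in untreated 93-11. There are no replicates within a group. Fitted changes below are limma estimates ± SE on the log2(RPKM + 1) scale over 4 libraries, with Benjamini-Hochberg adjusted p, and levels are TMM-scaled RPKM.

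The first question was which transcripts moved with chilling in both cultivars. Of the fixed lists, light-harvesting genes had the lowest median change (-5.82), and 7 of 10 chlorophyll synthesis genes fell. All 10 measured members of the list of other transcription factors reported in cold signalling rose. So did all 3 kinases reported in cold signalling, 5 of 6 DREB genes and 10 of 13 jasmonate genes. Of 19466 genes tested, 4599 were higher and 4464 lower in the chilled libraries, so 50.7 percent of calls were higher. That split moved with the scaling: it was 38.0 percent with upper quartile scaling, 39.7 percent with the values as deposited and 70.6 percent when scaled to reference genes. These scalings moved the median of all genes by -0.24, -0.21 and 0.36 log2 units. The scaling to reference genes rests on ACT1, EF1A and GAPC alone. Of these, ACT1 was itself lower in the chilled libraries in the limma fit (-1.27, adjusted p = 0.00786). List medians below kept their sign over 6 scalings except where a range is given. The most raised genes without a checked name were LOC_Os11g10470 (8.32 ± 0.21) and LOC_Os11g12650 (7.81 ± 0.24), and the most lowered were LOC_Os03g56930 (-7.21 ± 0.53) and LOC_Os03g62670 (-6.52 ± 0.36).

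All 4 named light-harvesting complex genes, which encode the chlorophyll-binding antenna proteins of the photosystems, fell (4 adjusted over the list alone; median -5.82, percentile 0.0 among matched random lists). CAB1R (LOC_Os09g17740) went from 3900 to 14.8 RPKM in Nipponbare and from 4740 to 57.3 in 93-11, a fitted change of -7.14 ± 0.44 (adjusted p = 0.000951). CAB2R changed by -6.13 ± 0.35, Lhcb3 by -5.51 ± 0.35 and Lhcb2 by -4.31 ± 0.36. With members of unchecked name added, 11 of 11 measured light-harvesting genes fell, with a median of -4.96. In chlorophyll biosynthesis, 7 of 10 measured genes fell, 7 also adjusted over the list alone (median -1.94, percentile 0.0). They included the protochlorophyllide reductases PORA (-6.31 ± 0.29, from 1090 to 9.18 RPKM in Nipponbare) and PORB (-3.98 ± 0.23), the magnesium chelatase subunit CHLH (-3.11 ± 0.36) and HEMA1 (-1.71 ± 0.24), while CHLD (0.50 ± 0.25), CHLG (0.34 ± 0.21) and GSA (0.56 ± 0.23) did not pass the test. Of 3 nuclear photosystem and electron transport genes, PetE, which encodes plastocyanin (-2.23 ± 0.33), and PsaH (-1.93 ± 0.41) fell, 2 also adjusted over the list alone, and LFNR1 did not pass (adjusted p = 0.559; list median -1.93, percentile 1.8). Counting also members of unchecked name, 12 of 14 fell. Neither of 2 Calvin cycle genes of checked name passed over all genes or adjusted over the list alone (median -1.19, percentile 9.6). With members of unchecked name added, 5 of 11 fell and 0 rose (median -1.51, percentile 0.1). RCA, Rubisco activase, had -1.92 ± 0.63 (adjusted p = 0.057) and passed under 6 of 10 alternatives, with adjusted p from 0.00068 to 0.466 over them. The plastid fructose-bisphosphatase gene cpFBPase had -0.47 ± 0.27 (adjusted p = 0.205), and passed with values as deposited (0.0489, the lowest of a range up to 0.977).

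**Figure D1:**
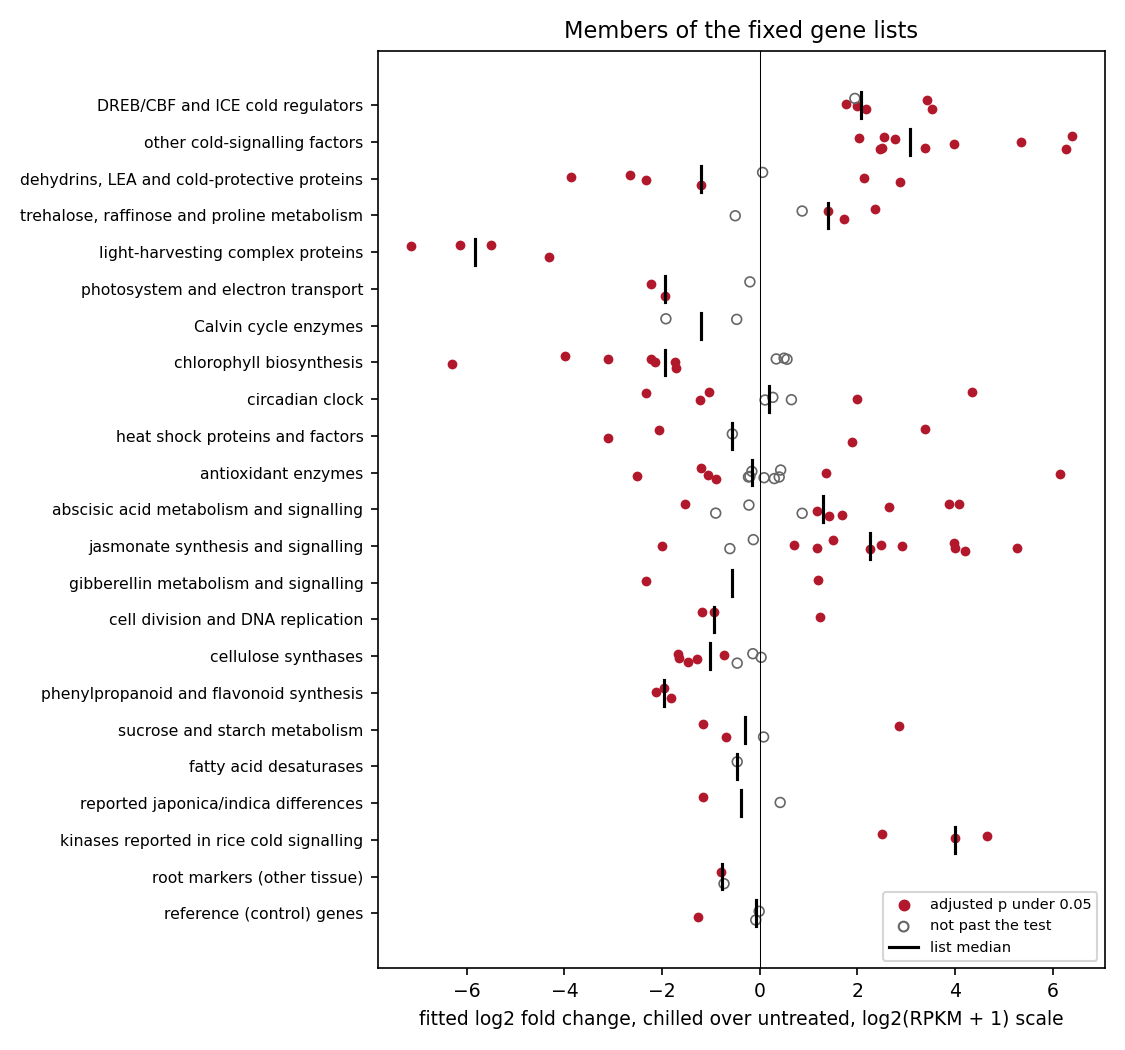
Fitted log2 fold change (x axis, chilled over untreated on the log2(RPKM + 1) scale) of each measured member of the fixed gene lists (rows), filled where the adjusted p was under 0.05, with the list median as a bar. Light-harvesting members lie between -7.14 and -4.31, and the cold-signalling factors lie above 0.

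Of the list of DREB and ICE regulators, the 6 measured genes of checked name were all DREB genes, which include the DREB1 factors that bind cold-response promoter elements. Of these, 5 rose and 6 did so adjusted over the list alone (median 2.08, percentile 99.9). OsDREB1B (3.53 ± 0.58, adjusted p = 0.00795) went from 0.49 to 6.59 RPKM in Nipponbare and from 0.81 to 46.4 in 93-11. OsDREB1A had 3.43 ± 0.44, OsDREB2A 1.99 ± 0.26 and OsDREB2B 1.77 ± 0.46. The last had adjusted p = 0.029, a call lost with values as deposited and without the cultivar term (range over alternatives 0.0035 to 0.168). OsDREB1G had 1.95 ± 0.64 (adjusted p = 0.0553) and passed with a pseudocount of 0.1 and with voom (range over alternatives 0.00438 to 0.178). All 10 other cold-signalling transcription factors measured rose, also adjusted over the list alone (median 3.08, percentile 100). Of 20 when members of unchecked name are included, 18 rose and 1 fell. OsNAC3 (LOC_Os07g12340) had 6.39 ± 0.30, OsWRKY71 6.27 ± 0.23, OsMYB4 5.35 ± 0.25, OsNAC6 2.77 ± 0.26 and OsMYBS3 2.50 ± 0.23. All 3 kinases reported in rice cold signalling rose, also adjusted over the list alone (median 3.99, percentile 99.9). CPK13, a calcium-dependent protein kinase, had 4.65 ± 0.23, MAPK5 3.99 ± 0.26 and MKK6 2.50 ± 0.22.

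In jasmonate synthesis and signalling, 10 of 13 measured genes rose and 1 fell, with the same counts adjusted over the list alone (median 2.25, percentile 100). The TIFY genes, which encode jasmonate signalling repressors, included TIFY11D (5.27 ± 0.23), TIFY11C (4.21 ± 0.29), TIFY11A (4.01 ± 0.29), TIFY10A (2.25 ± 0.22) and TIFY10B (1.17 ± 0.23). TIFY10C did not pass (-0.61 ± 0.25, adjusted p = 0.102), at 6.76 against 11.51 RPKM in Nipponbare and 5.87 against 8.97 in 93-11, chilled against untreated. The gene that fell was AOC, allene oxide cyclase of jasmonate synthesis (-2.0 ± 0.26). TIFY10C and AOC were chosen after their values were seen. TIFY11A had 1 read in untreated Nipponbare, and its log2 ratio there was 7.57 with a counting interval from 5.66 to 13.46. Of 10 abscisic acid genes, 6 rose and 1 fell, with the same counts adjusted over the list alone (median 1.30, percentile 98.2). ABA8ox1, which encodes an abscisic acid 8'-hydroxylase, had 4.08 ± 0.32 and PP2C68, a protein phosphatase 2C, 3.87 ± 0.27. PP2C06 rose by 1.17 ± 0.31 (adjusted p = 0.0303), a call lost under 4 alternatives (range 0.00706 to 0.0642). ZEP, zeaxanthin epoxidase, fell by 1.52 on the log2 scale (SE 0.25). Of 2 gibberellin genes, the synthesis gene GA20ox2 fell (-2.32 ± 0.32) and the DELLA repressor gene SLR1 rose (1.20 ± 0.22), both also adjusted over the list alone (median -0.56, percentile 25.6). Including members of unchecked name, 2 of 5 rose and 2 fell (median -1.26, percentile 3.8). The median log2 ratio of these 5 was -0.38 in Nipponbare (percentile 48.6) and -3.05 in 93-11 (percentile 0.1).

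Dehydrin, LEA and cold-protective genes went both ways. Of 7 measured, 2 rose and 4 fell, also adjusted over the list alone (median -1.21, percentile 1.9). With members of unchecked name added, the median was 0.06 (percentile 55.9), and with no filter on low values it was -0.01. LIP9 rose by 2.88 ± 0.33 and OsLti6b by 2.14 ± 0.35, while RAB16A had -3.87 ± 0.56 and OsLEA3-1 -2.32 ± 0.54. In trehalose, raffinose and proline metabolism, 3 of 5 rose, 4 adjusted over the list alone (median 1.4, percentile 97.9), with OsTPP2 at 2.37 ± 0.28, OsTPP1 at 1.72 ± 0.26 and RafS at 1.4 ± 0.22, and P5CS1 at 0.87 ± 0.30 (adjusted p = 0.0637, range over alternatives 0.0154 to 0.164). Including members of unchecked name, 4 of 9 rose and 5 did not pass (median 0.87, percentile 92.8). Of 13 antioxidant genes, 2 rose and 4 fell, also adjusted over the list alone. Their median was -0.16 (percentile 13.9) and ranged from -0.44 to 0.30 over scalings. AOX1a, the alternative oxidase of mitochondria, rose by 6.15 ± 0.24, APX2 had -2.52 ± 0.23 and CATA -1.06 ± 0.26, a call lost when scaled to reference genes and with no filter (range over alternatives 0.00575 to 0.0919). APX8 had 0.09 ± 0.41 (adjusted p = 0.873). Of 5 heat shock genes, 2 rose and 2 fell, also adjusted over the list alone (median -0.56, percentile 20.7), with HsfC1b at 3.39 ± 0.27, HsfA2d at -3.10 ± 0.33 and HSP90-2 at -0.56 ± 0.24 (adjusted p = 0.109, range over alternatives 0.0277 to 0.718). The reference entry matched for HsfA2d also carries the name ARD2, so its identity is uncertain. Over genes with a mean of at least 10 reads, the list's median relative to all genes was 0.08.

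Of 8 clock genes, 2 rose and 3 fell, also adjusted over the list alone. Their median was 0.19 (percentile 37.9) and ranged from -0.13 to 0.64 over scalings. Including members of unchecked name, 5 of 12 rose and 3 fell (median 0.46). OsLUX, an evening gene, rose by 4.34 ± 0.52 and OsPRR1 by 2.0 ± 0.34. OsLHY, a morning gene, had -2.32 ± 0.42 (adjusted p = 0.0101), and OsPRR95 had 0.65 ± 0.27 (adjusted p = 0.1, range over alternatives 0.0193 to 0.334). The labels give no harvest hour. Of 8 cellulose synthases, 5 fell, also adjusted over the list alone (median -1.01, percentile 0.5), among them CESA3 (-1.68 ± 0.24) and CESA7 (-1.65 ± 0.22), and CESA1 had -0.46 ± 0.22 (adjusted p = 0.147, range over alternatives 0.034 to 0.992). All 3 measured phenylpropanoid and flavonoid genes fell, also adjusted over the list alone (median -1.96, percentile 1.9), with CHS1, chalcone synthase, at -2.13 ± 0.31 and CHI at -1.96 ± 0.22. The list went both ways with members of unchecked name added: of 11 measured, 3 rose, 5 fell and 3 did not pass (median -0.69, percentile 3.7). Its median log2 ratio was then -0.96 in Nipponbare (percentile 1.5) and -0.20 in 93-11 (percentile 24.6). Of 4 sucrose and starch genes, 1 rose and 2 fell, also adjusted over the list alone. Their median was -0.30 (percentile 26.6) and ranged from -0.61 to 0.16 over scalings. The amylase gene RAmy3D had 82 reads in chilled Nipponbare and 0 in untreated Nipponbare, at least 32.5-fold higher against 3 reads. In 93-11 it had 478 and 3 reads, a log2 ratio of 7.67 (counting interval 6.34 to 10.18). GBSSI fell (adjusted p = 0.0131), with 3 reads in chilled and 60 in untreated Nipponbare, a log2 ratio of -3.86 (-6.39 to -2.45). SUS2 had -0.68 ± 0.21 (adjusted p = 0.046), a call lost under 5 of 10 alternatives (range 0.0136 to 0.417), and SUS1 had 0.08 ± 0.22.

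Only 3 of 12 named cell division genes passed the filter of the test, and the rest had reads but fell below it. Of the genes tested, CDKB2;1 rose (1.24 ± 0.30) and PCNA (-1.18 ± 0.26) and CDKB1;1 (-0.93 ± 0.28) fell, also adjusted over the list alone (median -0.93, percentile 16). With members of unchecked name added, the medians were 0.14 for cell division and 0.45 for the desaturases. PCNA lost the call when scaled to reference genes and with no filter (range over alternatives 0.0108 to 0.091), CDKB2;1 with no filter (0.0102 to 0.0671) and CDKB1;1 under 5 of 10 alternatives (0.0206 to 0.219). The 1 named fatty acid desaturase, SSI2, had -0.46 ± 0.23 (adjusted p = 0.152, range over alternatives 0.034 to 0.998, percentile 27.7) and did not pass adjusted over the list alone either. Of 2 genes reported to differ between japonica and indica, GBSSI fell and COLD1 had 0.42 ± 0.23 (adjusted p = 0.199, range over alternatives 0.0392 to 0.696), with 1 lower gene also adjusted over the list alone (median -0.38, percentile 31.8). Including members of unchecked name, 1 of 6 rose and 3 fell. Root markers were low in these aerial samples: HKT2;1 fell by 0.80 on the log2 scale (adjusted p = 0.0496, lost under 5 of 10 alternatives, range 0.0296 to 0.182), also adjusted over the list alone, and LSI1 had -0.73 ± 0.41 (median -0.76, percentile 23.3). Both shoot meristem markers, OSH1 and OSH15, had at most 2 reads in any library and were not tested. Of 3 reference genes, ACT1 fell (-1.27 ± 0.21, adjusted p = 0.00786), also adjusted over the list alone, and GAPC had -0.08 ± 0.27. The reference list's median was -0.08 (percentile 27.6) and ranged from -0.40 to 0.38 over scalings. In the lists whose counts with members of unchecked name are not given above, 5 of 7 DREB and ICE genes rose, 9 of 12 chlorophyll synthesis genes fell, 11 of 14 jasmonate genes rose and 1 fell, and 9 of 14 abscisic acid genes rose and 1 fell. Of 9 dehydrin and LEA genes 2 rose and 4 fell, of 18 antioxidant genes 4 and 5, of 7 heat shock genes 2 and 3, and of 6 sucrose and starch genes 2 and 3. Of 5 cell division genes 1 rose and 2 fell, of 6 desaturases 1 and 1, and of 4 reference genes 0 and 2. Without the cultivar term, limma's calls ended for OsDREB1B (range of adjusted p over alternatives 0.000133 to 0.0575), OsDREB1C (0.00448 to 0.0533, lost also with no filter), OsWRKY76 (0.000302 to 0.108), OsLEA3-1 (0.000666 to 0.202), ABA8ox1 (6.86e-06 to 0.0616), SLR1 (0.00224 to 0.0679) and RAmy3D (1.91e-05 to 0.0629). With no filter the call ended for PsaH (0.000583 to 0.0865).

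The next question was how the cultivars' responses compared. By size, 3742 genes were higher and 3412 lower in chilled than in untreated Nipponbare, and 3810 higher and 3271 lower in 93-11. These majorities depended on the scaling. With upper quartile scaling 2890 were higher and 4686 lower in Nipponbare, and 3048 and 4428 in 93-11. With values as deposited the counts were 2884 and 4707 in Nipponbare, and 3258 and 4059 in 93-11, and when scaled to reference genes 4842 and 2477, and 5773 and 1733. Both cultivars shared 2909 of the higher genes and 2314 of the lower, where independent lists would share 732 and 573. That expectation treats all genes alike. Genes of many reads enter either list more readily, so shared read depth by itself would raise the overlap above it. Only 8 genes were higher in chilled Nipponbare and lower in chilled 93-11, and 9 the reverse. Across genes, which are not independent replicates, the log2 ratios of the cultivars had Pearson r 0.858 and Spearman rho 0.836, and 83.6 percent had the same sign.

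**Figure D2:**
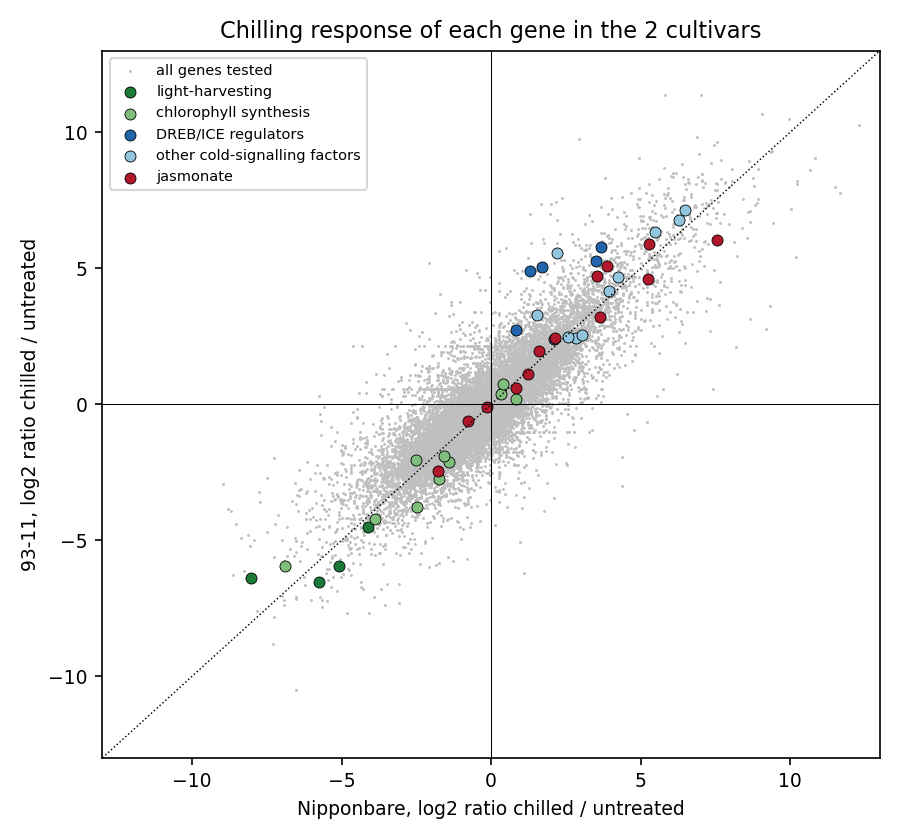
Log2 ratio of chilled to untreated reads in Nipponbare (x axis) and 93-11 (y axis) for each of 19466 genes in grey, with 5 fixed gene lists in colour and the line of equal response dotted. Several DREB regulators lie above the line, such as OsDREB1G at 1.29 and 4.91.

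The regulators OsDREB1G and OsDREB1C and the factor OsWRKY76 led the named genes with larger chilled-to-untreated ratios in 93-11. The response was higher in 93-11 than in Nipponbare by size for 687 genes and lower for 512, with no test and no replicate check. The counts were 856 and 406 with values as deposited, and 1131 and 310 when scaled to reference genes. OsDREB1G had a log2 ratio of 1.29 in Nipponbare and 4.91 in 93-11, a difference of 3.63 (counting interval 2.21 to 5.05). OsWRKY76 had 2.19 and 5.58, OsDREB1C 1.71 and 5.03, OsLUX 4.00 and 5.96, OsDREB2B 0.85 and 2.75, and OsPRR1 1.46 and 2.69. In untreated Nipponbare and 93-11, OsDREB1G had only 10 and 9 reads, and OsDREB1C 19 and 6. For OsDREB1C the difference was 3.32 (1.97 to 4.68), and part of it came from the untreated libraries. Its log2 ratio of 93-11 over Nipponbare was -1.87 (-3.56 to -0.56) untreated and 1.46 (1.00 to 1.95) chilled. OsLEA3-1 had -3.67 in Nipponbare and -1.63 in 93-11, from levels of 54.8 and 5.23 RPKM in untreated seedlings, and CAB1R had -8.03 and -6.37. In the other direction, NCED3, which encodes a rate-limiting enzyme of abscisic acid synthesis, had 3.04 in Nipponbare and 0.93 in 93-11, a difference of -2.11 (-2.52 to -1.69). Its fitted change was 1.69 ± 0.47 (adjusted p = 0.0339), a call lost under 4 alternatives (range 0.00535 to 0.0664). OsLHY had -1.56 and -3.09, CHLH -2.49 and -3.79, and bZIP23 1.51 and 0.28. The interval of the bZIP23 difference (-1.23) no longer lay beyond 2-fold under 4 of 8 alternatives (differences -1.23 to -0.97), nor did those of CHLH (-1.30) and OsLti6a (-1.39) when scaled to reference genes (-1.03 and -1.13). The ascorbate peroxidase gene APX8 had 0.83 and -0.65, and the membrane protein gene OsLti6a 0.76 and -0.63. When scaled to reference genes, the 93-11 ratios were -0.05 (-0.10 to -0.01) for APX8 and -0.03 (-0.13 to 0.07) for OsLti6a. The 6 DREB genes had a median of 1.90 in Nipponbare (percentile 99.3) and 4.97 in 93-11 (percentile 100).

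**Figure D3:**
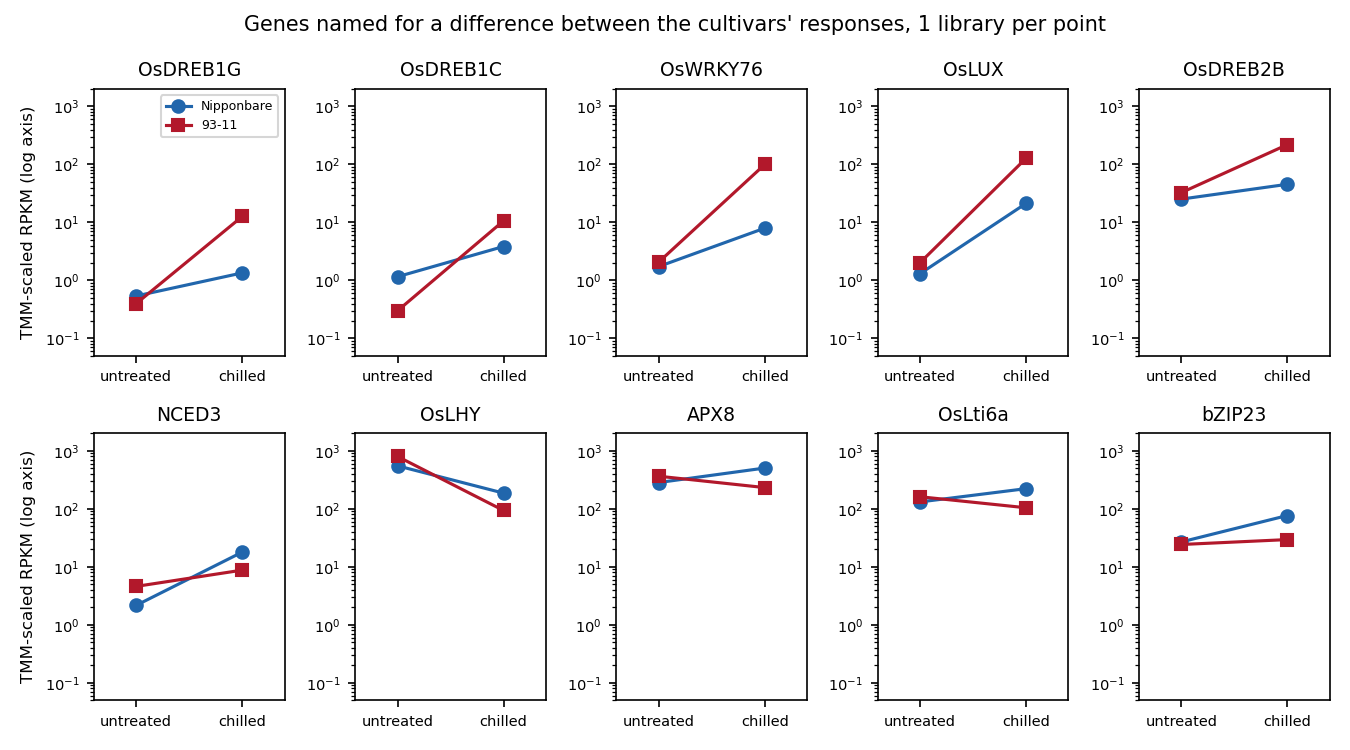
TMM-scaled RPKM (log axis) of 10 genes named for a difference between the responses, in untreated and chilled seedlings of Nipponbare (circles) and 93-11 (squares), 1 library per point. OsWRKY76 went from 1.74 to 7.98 in Nipponbare and from 2.08 to 100.1 in 93-11, and APX8 went from 363 to 231 in 93-11.

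The last question was which genes differed between cultivars in both conditions. Among named genes the abscisic acid hydroxylase gene ABA8ox1 passed the test, at 2.23 ± 0.32 higher in 93-11 (adjusted p = 0.0239), with 1.56 against 7.27 RPKM in untreated and 29.0 against 202 in chilled seedlings. No named gene met the rule for this comparison, which asks for 10 RPKM in both conditions, and ABA8ox1 was chosen after its values were seen. No other of the 126 tested genes with a checked name passed, against 1143 of all 19466 genes. The cultivar call of ABA8ox1 was not followed gene by gene over the alternatives. Of 19466 genes, 324 were higher and 819 lower in 93-11. Without the treatment term limma called 0 genes, with 1240 at an unadjusted p under 0.05. That fit counts the chilling effect as spread between libraries, so its 0 calls cannot decide whether the cultivar differences hold. Among genes without a checked name, LOC_Os06g38210 had 317 RPKM in untreated Nipponbare and 0.82 in untreated 93-11 (-7.36 ± 0.22), and LOC_Os09g32169 had 985 reads in untreated Nipponbare and 0 in both libraries of 93-11. LOC_Os09g10340 was higher in 93-11, at 0.22 against 135.5 RPKM untreated, as was LOC_Os03g17410, at 0.02 against 18.96. By size, 603 genes were higher and 1237 lower in 93-11 among untreated seedlings, and 1194 higher and 1552 lower among chilled seedlings, with 359 higher and 903 lower in both. When scaled to reference genes the majority among chilled seedlings turned, with 1793 higher and 1206 lower in 93-11. In chilled Nipponbare and 93-11, EF1A had 46.6 and 30.4 RPKM, GAPC 287 and 237, and ACT1 24.4 and 25.4. That turn thus rests mostly on EF1A. With at least 10 reads in both libraries of 1 cultivar, 339 genes had no reads in 93-11 and 117 had none in Nipponbare.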

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

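The tests of scaling, green tissue and clock below, and that of genes with at least 10 reads, were chosen after the results were seen; those of gene length and of genes with any reads were written before.

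Of 126 tested genes with a checked name, 6 had counting intervals on opposite sides of 0 in the cultivars. OsGI, APX8, OsLti6a and GAPC were higher in chilled Nipponbare and lower in chilled 93-11, and CESA5 and SODCC2 the reverse. The difference of the log2 ratios, 93-11 minus Nipponbare, was -0.32 for OsGI, -1.48 for APX8, -1.39 for OsLti6a, -0.43 for GAPC, 0.75 for CESA5 and 1.19 for SODCC2. These differences were not tested, since each rests on 1 library per group. The scaling moved these sides: over 6 scalings the intervals lay on opposite sides of 0 in 6 for APX8, 5 for OsLti6a, 5 for SODCC2, 4 for CESA5, 3 for GAPC and 2 for OsGI. When scaled to reference genes, the ratio in 93-11 was -0.05 (-0.10 to -0.01) for APX8, -0.03 (-0.13 to 0.07) for OsLti6a and 0.30 (0.25 to 0.35) for GAPC. The differences ranged over scalings from -1.48 to -1.22 for APX8, -1.39 to -1.13 for OsLti6a, -0.43 to -0.16 for GAPC, -0.32 to -0.06 for OsGI and 1.19 to 1.45 for SODCC2, and were 0.75 or more for CESA5.

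The fall of light-harvesting genes was weighed first. The list's median stayed at or below -5.36 over 6 scalings, which argues against scaling as the cause. A smaller share of green tissue in the chilled pools would lower photosynthesis transcripts alike, but the light-harvesting and Calvin cycle medians, over members of which only 4 of 11 and 2 of 11 had checked names, lay 3.45 log2 units apart (-4.96 and -1.51), against at most 0.98 between cultivars. The 7351 genes of similar length (1075 to 1901 bases) had a median of -0.09. That range spans the median length of 1485, so scaling held their median near that of all genes (-0.06). It is a weak test by itself. Across genes tested, recovered length and fitted change had a Spearman correlation of 0.05, which argues against length bias. This correlation was not part of the test written beforehand. Chilling itself remains as a hypothesis, with harvest hour open since many of these genes follow the day. Chilled seedlings had also left the greenhouse. Any other condition that differed after the move, light included, cannot be told apart from temperature.

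More genes were lower than higher in 93-11. Over 6 scalings the ratio of lower to higher was at least 2.37 for fitted calls and 2.0 by size in untreated seedlings, which argues against scaling there. By size in chilled seedlings it fell to 0.67 with reference genes. The other scalings kept a small majority lower in chilled seedlings, from 1552 lower and 1194 higher with TMM to 1478 and 1268 with TMM without the 50 most abundant genes. Scaling stays open for that part. If reads of 93-11 were lost on gene models of another cultivar, genes silent in 93-11 alone should outnumber the reverse by more than 1.5 times. The ratio was 1.19 for genes with any reads, which met the bound written against this explanation, but 56.3 percent of those genes had under 10 reads in both Nipponbare libraries, where a 0 can be chance, and with at least 10 reads it was 2.9. Lost reads and a true difference in gene content or expression cannot be told apart here, since the mapping reference is not given in the sources used here.

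Morning and evening clock genes moved apart, with OsLUX minus OsLHY changing by 6.66 log2 units, and that difference varied by 0.16 over 6 scalings. A library's factor nearly cancels in a difference of 2 of its genes, so this range was bound to be small and is no test. For the same reason scaling could not part the 2 genes by 6.66. Over 10 alternatives, other scalings among them, OsLUX stayed at 4.08 or more and OsLHY at -1.86 or less. This argues against scaling for these 2 genes. A harvest at another hour could move the whole clock, but OsGI, another evening gene, had a fitted change of 0.11 (log2 ratios 0.60 and 0.54 when scaled to reference genes), and 2 of 4 evening genes moved by under 0.5 in both cultivars. A gene sampled on either side of its peak can sit at the same level, so with 1 time per condition a shifted clock and a direct effect of chilling cannot be told apart.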

How the results depend on the processing

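Reference-gene scaling of the counts of genes, voom weights, named genes without the other factor, and lists with unchecked members were added after the data were seen. The planned edgeR and DESeq2 tests were not run, since the files hold RPKM, and gene families by description were not run. The reported fit is paired by cultivar through its cultivar term, and by condition for the cultivar comparison; the fits below without the other term are those with no replicate block. With 1 library per group there are no replicate numbers to pair, and leaving out a library leaves no residual degrees of freedom. Depth limits genes of few reads, whose intervals are wide.

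Genes lower in the chilled libraries numbered 4464, against 2500 when scaled to reference genes and 2742 with no replicate block (no cultivar term). Of these, 2499 and 2740 were among the 4464. Cultivar calls, 324 higher and 819 lower in 93-11, became 494 higher with a pseudocount of 0.1, 82 and 294 with no filter, 176 and 515 with a mean of at least 10 reads, 682 and 1249 with voom, and 0 and 0 with no replicate block (no treatment term). No call of either kind changed direction under any alternative run. With the 4-fold bound, counts were 1693 higher and 1177 lower for chilling in Nipponbare, 1810 and 1072 in 93-11, 242 and 746 for the cultivars untreated, 364 and 784 chilled, and 120 and 86 for the response difference. When scaled to reference genes, counts by size were 5773 higher and 1733 lower for chilling in 93-11, 1793 higher for chilled 93-11 over Nipponbare, and 1131 and 310 for the response difference. With no filter, 962 genes were higher and 1929 lower in untreated 93-11. The same-sign share was 84.5 percent with upper quartile scaling, 84.3 as deposited, 83.0 with reference genes and 82.7 with a mean of at least 10 reads. Pearson r and Spearman rho were 0.869 and 0.844 with a prior of 2 reads, and 0.818 and 0.809 with a mean of at least 10 reads. With no filter, the same-sign share was 70.1 percent, r 0.649 and rho 0.583. The fits with no replicate block count the effect of the term left out as spread. The cause of the other moves was not tested.

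List medians relative to that of all genes changed as follows. With unchecked members added they were 0.12 for dehydrins (reversed), 0.20 for cell division (reversed), 0.51 for desaturases (reversed), 0.92 for trehalose and raffinose, -4.90 for light-harvesting, -1.45 for the Calvin cycle, 0.51 for the clock, 1.93 for jasmonate, -1.21 for gibberellin, -0.64 for flavonoids, -0.85 for japonica and indica genes and -0.46 for reference genes. With a mean of at least 10 reads, heat shock genes had 0.08 (reversed) and cell division -0.34; with no filter, dehydrins had 0.01 (reversed), trehalose and raffinose 1.15, heat shock genes -0.01 and cell division -0.16. These settings change the members counted. With a pseudocount of 0.1, the other transcription factors had 4.02, gibberellin -1.09 and japonica and indica genes -1.22. With reference genes, flavonoids had -1.80, sucrose and starch -0.14 and japonica and indica genes -0.38, and sucrose and starch had -0.31 with upper quartile scaling. With a prior of 2 reads, japonica and indica genes had -1.36 in Nipponbare and -1.39 in 93-11. Other counts of fitted calls and of genes by size stayed within 1.5 times of those reported, thinning to the smallest total included. Counts shared by both cultivars or both conditions, and those of genes without reads, were not part of this comparison. Among fitted changes of named genes, 759 values stayed on their side of the threshold, 22 gained and 39 lost the call, and 0 changed direction while called. Of their response differences, 99 values stayed within the counting interval reported and 13 moved beyond it, with 0 changing sign.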

Other observations

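The neighbour tests in this part were written before their results were seen.

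The LEA gene OsLEA3-2, chosen after its values were seen, stood at 15.5 RPKM (250 reads) in chilled Nipponbare. It had 13 reads in untreated Nipponbare, 8 in chilled 93-11 and 21 in untreated 93-11, and was below the filter of the test. The small heat shock gene HSP16.9B, also chosen afterwards, had 36 reads in chilled Nipponbare, 7 in untreated Nipponbare, 0 in chilled 93-11 and 5 in untreated 93-11. OsDREB1H, a neighbour of OsDREB1A and OsDREB1B chosen in the same way, had 26 reads in chilled 93-11, 3 in chilled Nipponbare, 4 in untreated Nipponbare and 0 in untreated 93-11. Also chosen afterwards, the DNA replication genes MCM2, MCM3, MCM4, MCM5, MCM6 and MCM7 had at most 0.71 RPKM in any library.

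A hypothesis was that neighbouring genes respond alike. Fitted changes of 19439 pairs of adjacent tested loci, ordered by identifier, had a rank correlation of 0.122, above the highest of 10000 shuffles within chromosomes (0.03). It fell to 0.051 for loci 2 apart and 0.006 for loci 10 apart. Reads shared by tandem copies could add to the 0.122 and were not tested.

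A second hypothesis was that genes without reads in 93-11 lie in blocks. Among 18040 loci with at least 10 reads in both Nipponbare libraries, 339 had none in 93-11, and 43 pairs of these were adjacent, against a mean of 7.8 and a maximum of 19 in 10000 shuffles. The longest run was 4 loci. Adjacent here means next in identifier order among those 18040 loci. Missing or diverged segments, reads dropped at near-identical copies, or neighbouring genes silent together in 93-11 could each give such clusters. These data cannot separate them from each other.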
